A study of Callithrix jacchus with 24 samples.

How the data were processed

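The deposited RNA files are Cell Ranger tables of genes by barcodes and hold raw counts of unique molecular identifiers (UMIs), per the file headers and the labels. Per the authors' processing notes they were made with cellranger 6.0.1. The file headers carry version 6.0.1 for the nuclei of Adult3, version 3.0.2 for the libraries of Neonate2 and no version for the others, so the version could differ between animals. Each library of cells holds 8000 barcodes and the library of nuclei 3241. The chromatin files hold raw counts of transposase insertion sites per peak and cell from cellranger-atac 2.1.0, per the authors, and most entries are even. Genes carry NCBI gene identifiers with symbols. The annotation release and the genome build are not given in the sources used here, so genes are named by symbol and identifier, and peaks by chromosome and position.

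The design was fixed before the data were examined. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored in each library by comparing each cell with simulated pairs of cells, and the highest 5% of scores were removed. Of 155241 barcodes, 118930 passed the filter, 5959 were removed as predicted doublets and 112971 remained. Free RNA was not subtracted. The cells of each animal were clustered apart from those of other animals, on 2000 variable genes and 40 principal components, with 20 neighbours and Leiden resolution 1.0, with seed 1. This gave 216 clusters over 5 animals.

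Clusters were named from marker lists of the retinal classes. A class name needed at least 3 raised markers, where raised meant at least 1 log2 unit above the median cluster and present in at least 10% of cells, and a margin of 1.0 log2 unit over the next class. Clusters in which at least 50% of cells were predicted doublets, and clusters without a clear class, stayed unnamed. These naming thresholds were set after the clusters had been seen. Cells are called cone-like, rod-like and so on by this rule, and the plain class name is used from here on. No name rests on a protein or on position in the tissue.

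UMIs were summed over the cells of a class in each unit, and a unit needed at least 20 cells. For fovea against periphery in neonates the unit was an animal and region, with animal as the block. For adult against neonate fovea the unit was an animal. For fovea against periphery in adults the unit was a library, because only Adult2 has both regions. Rods and retinal ganglion cells (RGCs) of neonates were not tested, because not every animal and region had 20 of them. The foveal rods numbered 18 in Neonate1 and 0 in Neonate2, and Neonate1 had 3 peripheral RGCs. A test of RGCs among the libraries of Neonate2 alone was not run. The CD90-positive library of the neonate, the adult library labelled CD70p and the NeuN-positive nuclei were left out of these tests, since their enrichment differs from that of the CD73-depleted libraries. The library labelled CD70p carries CD90 in the name of its deposited file, and which of them is right was not settled here. The technical replicates of Neonate1 fovea replicate 2 were added together.

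The model was the quasi-likelihood F test of edgeR 4.0.16, with TMM scaling and its expression filter, and p values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called at an adjusted p under 0.05. All adjusted p values of genes in the text come from edgeR. The standard error (SE) of a log2 fold was derived as the absolute log2 fold over the square root of the edgeR F value. It is approximate, and can be too small where a group holds few UMIs. Levels in CPM, the UMIs of a gene scaled by the TMM-adjusted total of its unit, are means over the units of a group. Summed markers, levels across classes and levels given per animal are scaled by the plain total. Genes with 0 UMIs in a group are given as a lower bound that puts 3 UMIs in that group. Genes with 1 to 3 UMIs in a group are given as a ratio with an exact binomial 95% interval. Intervals of shares are exact Clopper-Pearson 95% intervals. Intervals of Spearman's rho use Fisher's z over genes. Intervals and bounds cover counting error only.

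Named genes were picked by a fixed rule, and only genes with a symbol could be named. For neonate cones and Müller glia the rule took the 10 largest log2 folds per direction among genes with adjusted p under 0.05, one sign in both animals and at least 20 CPM in the higher region. For the other comparisons it took 4 per direction with one sign in every pair of units. To these were added up to 4 members per gene list and direction by adjusted p. Some genes that the rule picked are not used here. For each named gene the mean level in the other classes was computed, and a gene at least 5 times higher in another class is given with that class, since free RNA can carry such genes between cells.

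Gene lists were written before the files were read, and 25 were used. They are cone phototransduction, rod phototransduction, visual cycle, retinoic acid metabolism and receptors, FGF signalling, WNT signalling and inhibitors, BMP and TGF-beta signalling, Notch signalling, thyroid hormone, regional transcription factors and guidance, Müller glia homeostasis, glial reactivity, photoreceptor synapse, outer segment and cilium, immature neuron and axon growth, neurofilament and mature excitability, glycolysis and hypoxia, angiogenesis and anti-angiogenic factors, extracellular matrix and adhesion, oxidative phosphorylation, cholesterol synthesis, cell cycle, dissociation and stress response, bipolar type genes, and RGC type genes. A list needed at least 3 measured members. Lists were tested with camera of limma 3.58.1 with the preset correlation of 0.01, and p values were adjusted over the lists of a comparison. The adjusted p of a list in the text is that of camera. Over 13 comparisons 324 list tests were made, and 127 passed with the preset correlation. With a correlation estimated from the data none of the 127 passed, and the lowest adjusted p was 0.0914. That second test has only the residual degrees of freedom of each fit, which are very few here. It could hardly pass any list, so its values do not tell whether a list changed. Counts of list members are given over all genes and adjusted over the list alone.

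The alternatives were no block for animal, libraries as units, RLE scaling, the Wald test of DESeq2 1.42.0, no expression filter, at least 1000 genes per cell, doublets kept, units thinned to 1182249 UMIs, leaving out 1 library or animal at a time, genes called the same way in 3 or more other classes left out, a minimum of 20 CPM for the comparison of ages, and for peaks a reciprocal overlap of 50% and the upper part of peaks by counts. Chosen after the data were seen were leaving out genes at least 5 times higher in another class, leaving out genes higher in adult rods, putting unnamed clusters back into classes, and replicate number as block in the adult. The model was tested on simulated data with 200 changed genes per comparison. A true log2 fold of 2 was recovered for 86% of genes or more in the neonate comparisons, for 2% to 54% in the age comparisons and for 65% to 99% in the adult comparisons. At most 6.9% of calls on simulated data were false. The simulation drew genes independently, with 1 dispersion per comparison and no effect of single libraries. It therefore cannot give the share of false calls in the real data.

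Clustering used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9. The models ran in R 4.3.3, overlaps of peaks in bedtools 2.31.1 and plots in matplotlib 3.10.9. Of the chromatin libraries, peak lists with counts were used for fovea replicate 1 and periphery replicate 2, and the peak positions of the other pair were not used here.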

Results

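The series measured gene expression in single cells and nuclei of the common marmoset (Callithrix jacchus) retina, and accessible chromatin in single nuclei. The fovea is the pit of the primate retina used for sharp vision, where cones are dense and rods are lacking at the centre. Foveal tissue was a central piece and peripheral tissue came from outside it. The data comprise 24 samples of 6 animals in 9 groups, of which 20 are RNA samples of 5 animals and 4 are chromatin samples of Neonate3. The peripheral cells had been sorted. Most of these libraries were depleted of CD73-positive cells, a surface protein of rods. Other peripheral libraries were enriched for CD90, for a label given as CD70p, which the name of the deposited file gives as CD90, or for NeuN, a nuclear protein of neurons. Neonate1 gave foveal replicates 1 and 2, the second in 3 technical replicates, and CD73-depleted peripheral replicates 1 and 2. Neonate2 gave foveal replicates 1 and 2, CD73-depleted peripheral replicates 3 and 4 and 1 CD90-positive library. Adult1 gave 3 foveal replicates. Adult2 gave 2 foveal replicates, 2 CD73-depleted peripheral replicates and 1 CD70p library, and Adult3 gave 1 library of NeuN-positive nuclei.

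Total UMIs per RNA sample ranged from 5691798 to 63852586, and the median UMIs per cell from 1403 to 10937. Neonate1 had 15169308 UMIs in foveal replicate 1, then 5691798, 7924312 and 6211344 in the technical replicates of foveal replicate 2. Its peripheral replicates had 21057130 and 21535989. Neonate2 had 52757155 and 46100776 in the fovea, 52574051 and 33647262 in CD73-depleted replicates 3 and 4, and 63852586 in the CD90-positive library. Adult1 had 21377727, 15336854 and 22114101. Adult2 had 23272387 and 23681166 in the fovea, 16302370 and 15895490 in the CD73-depleted periphery, and 39586254 in the CD70p library. The nuclei of Adult3 had 13468468. The chromatin samples had 3634180 and 31997852 counts in the fovea and 70559429 and 68771606 in the periphery.

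The first question was which cell classes each group held. In neonate fovea, bipolar cells made up 30.0% ± 4.41 (SD, n = 2 animals) of cells, RGCs 24.5% ± 3.03, cones 10.1% ± 0.11, amacrine cells 9.95% ± 1.89, horizontal cells 9.12% ± 3.2 and Müller glia 6.98% ± 2.88. In adult fovea, bipolar cells made up 37.3% ± 1.15 (SD, n = 2 animals), RGCs 21.2% ± 3.58, Müller glia 17.8% ± 0.927, amacrine cells 8.85% ± 0.313, horizontal cells 4.89% ± 1.34 and cones 4.86% ± 2.13. The Müller glia share lay between 4.94% and 9.01% in the neonates and between 17.2% and 18.5% in the adults. The cone share lay between 10.0% and 10.2% in the neonates and between 3.36% and 6.37% in the adults. No test was made of these shares. A comparison of 2 animals with 2 has a smallest two-sided exact p of 1 in 3.

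The peripheral libraries had been sorted, and sorting can set their class shares. Foveal libraries were not sorted. Region and sorting therefore cannot be told apart in the gene calls between regions, those of stress genes included. In the CD73-depleted periphery of Neonate1, bipolar cells were 46.1% (95% interval 45.3 to 46.9) of cells, Müller glia 13.0%, amacrine cells 12.9%, rods 10.2%, cones 9.15% and RGCs 0.0206% (0.00425 to 0.0602). Progenitor-like cells were 1.23% (1.06 to 1.42) there and were named in no other group. Replicate 4 of Neonate2 held 41.9% (40.7 to 43.0) bipolar cells, 17.9% cones, 14.3% rods and 0.984% (0.77 to 1.24) RGCs. Replicate 3 of the same animal and label held 56.2% (55.1 to 57.4) RGCs, 18.5% amacrine cells, 13.5% horizontal cells, 0.296% (0.186 to 0.448) bipolar cells and 0.0269% (0.00326 to 0.0972) rods. The CD73-depleted periphery of Adult2 held 50.4% (49.4 to 51.3) bipolar cells, 13.3% cones, 10.3% Müller glia, 9.0% rods and 0.508% (0.385 to 0.658) RGCs. The CD90-positive library of Neonate2 was 78.2% (77.1 to 79.3) mural cells and 5.34% (4.74 to 5.98) endothelial cells. The CD70p library was 60.1% (58.8 to 61.4) amacrine cells and 30.4% (29.2 to 31.6) RGCs. The NeuN-positive nuclei were 19.5% (18.1 to 20.9) RGCs, 12.6% (11.5 to 13.9) rods and 11.8% (10.7 to 13.0) amacrine cells. Foveal rods of the neonates were 0.0842% ± 0.119 (SD, n = 2 animals), and the 0 rods of foveal replicate 1 of Neonate1 allow a share of up to 0.0626%.

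**Figure D1:**
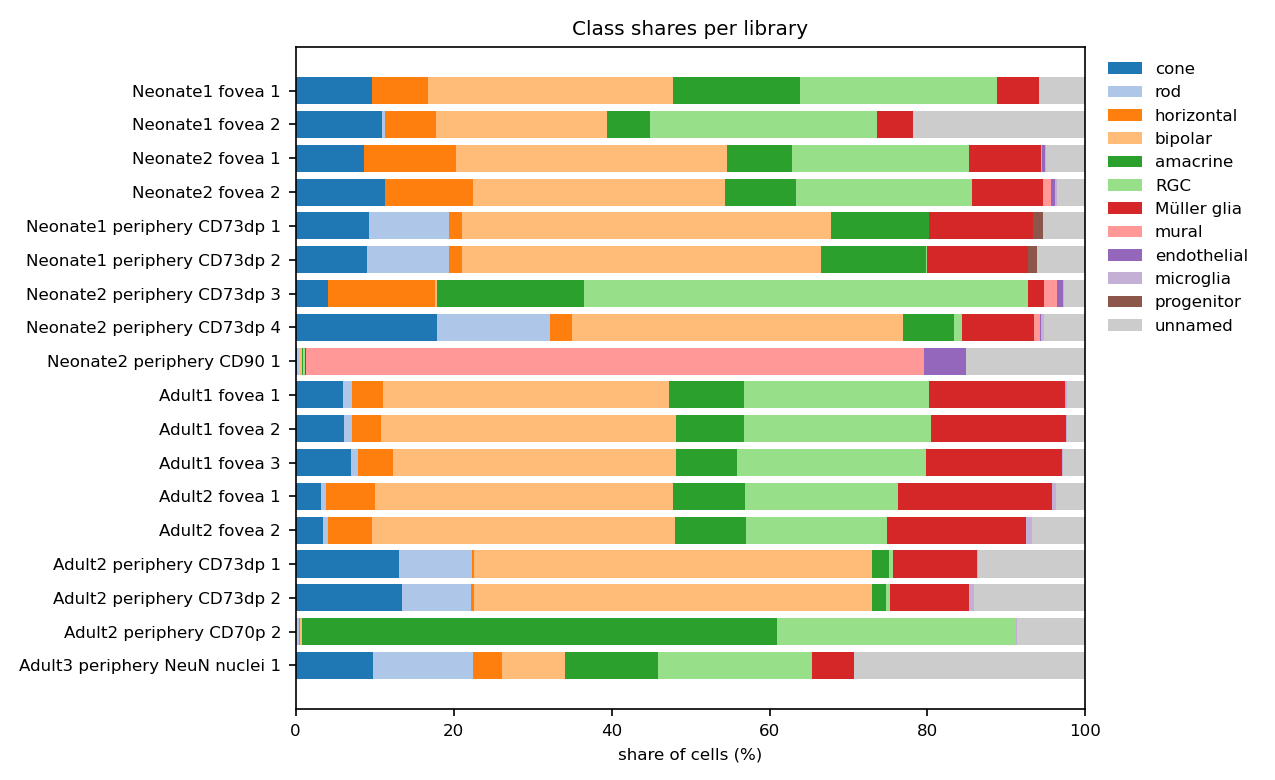
Share of cells in each class (percent, stacked bars), with 1 bar per library. RGCs make up 56.2% of CD73-depleted replicate 3 of Neonate2, and Müller glia lie between 17.2% and 18.5% in the 2 adult foveas and between 4.94% and 9.01% in the neonate ones.

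Unnamed cells made up 13.0% (12.4 to 13.7) of the fovea of Neonate1 and 5.75% (5.37 to 6.14) of its periphery. They made up 4.29% and 3.99% in Neonate2, 2.51% in Adult1, 5.21% of the fovea and 13.8% of the CD73-depleted periphery of Adult2, 15.1% of the CD90-positive library, 8.62% of the CD70p library and 29.3% of the nuclei. Unnamed groups included 658 cells nearest to cones in the fovea of Neonate1 (6.16% of that group), 731 nearest to amacrine cells in its periphery (5.02%), 1164 nearest to Müller glia in the periphery of Adult2 (10.4%), 619 nearest to mural cells in the CD90-positive library (11.8%), 377 nearest to RGCs in the CD70p library (6.56%) and 345 nuclei nearest to bipolar cells (11.4%). Fovea and periphery fell into different clusters for some classes. Cones of Neonate1 lay in cluster 8 in the fovea (99.5%) and in cluster 5 in the periphery (99.0%), and those of Neonate2 in clusters 4 (99.4%) and 2 (99.8%). Müller glia of Neonate1 lay in cluster 20 in the fovea (99.2%) and in clusters 4 (68.3%) and 19 (31.7%) in the periphery. Those of Neonate2 lay mostly in clusters 7 (86.4%) and 18 (81.9%). Horizontal cells of Neonate1 lay in cluster 14 in the fovea (98.5%) and in clusters 35 (53.3%) and 36 (41.0%) in the periphery, and those of Neonate2 mostly in clusters 3 (93.9%) and 13 (77.4%). In Adult2, Müller glia lay in cluster 1 in the fovea and in cluster 11 in the periphery, and cones in clusters 18 (99.4%) and 9 (91.3%). Bipolar cells were spread over several clusters, some of them of one region. In Neonate2, clusters 8, 15 and 23 were 99.0%, 99.0% and 98.7% foveal, and clusters 20, 31 and 35 were 3.47%, 0.79% and 0.86% foveal. In Adult2, bipolar cluster 6 was 98.7% foveal, and clusters 19 and 21 were 4.02% and 0.37% foveal. The leading amacrine cluster of Neonate2 was cluster 40 in the fovea (20.7%) and cluster 12 in the periphery (46.0%).

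The second question was how cones of the neonate fovea differ from peripheral cones. The test had 2 animals with both regions, and cones numbered 1089 and 1332 in Neonate1 and 1469 and 1614 in Neonate2 for fovea and periphery. Of 13744 genes, 910 were higher and 767 lower in foveal cones. The count was 699 without CD73-depleted replicate 4 of Neonate2 and 2886 without replicate 3. SPON2 (gene 103792151), a secreted matrix protein, fell by 9.10 log2 units (SE 0.315, adjusted p = 0.000144). ALDH1A3 (gene 100397394), which makes retinoic acid, was lower by a ratio of 499 (89.0 to 19700.0), with 34.6 CPM in the periphery. CDKN2C (gene 100395956), an inhibitor of cyclin-dependent kinases, was lower by a ratio of 353 (97.2 to 2920.0). FAM105A (gene 100401083) was lower by a ratio of 183 (62.2 to 890.0) and ATP6V1B1 (gene 100400819), a subunit of the proton pump, by 101 (34.3 to 495.0). INSM1 (gene 100398693), a zinc-finger factor of newborn neurons, had a log2 fold of -7.05, FTCD (gene 100408734) -7.15 and GSG1 (gene 100385120) -6.06.

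Among genes higher in foveal cones, VAV3 (gene 100390165), a guanine nucleotide exchange factor, led with a ratio of 170 (46.7 to 1410.0). DCLK2 (gene 100401840), a kinase that binds microtubules, rose by 6.32 (SE 0.299, adjusted p = 0.000168), from 1.16 to 103 CPM. The sorting receptors SORCS3 (gene 100408455) and SORCS1 (gene 100402398) rose by 6.30 and 4.84, and PKIA (gene 100386483), an inhibitor of protein kinase A, by 5.26 (SE 0.209, adjusted p = 0.000147) to 297 CPM. SLC24A1 (gene 100415019), the sodium and calcium exchanger best known from rods, rose by 4.89 (SE 0.432). The others of the 10 largest were ARHGEF26 (gene 100389856) with a log2 fold of 5.93, PLA2G5 (gene 100410471) with 5.36, CNTNAP5 (gene 100387366) with 5.02 and PTPRK (gene 100394114) with 4.88. RDH12 (gene 100403102), a retinal reductase of photoreceptors, rose by 2.15 (SE 0.184, adjusted p = 0.00103), and TTR (gene 100414809), a carrier of thyroid hormone and retinol, by 2.18 (SE 0.22, adjusted p = 0.00165). CNGB3 (gene 100402067), a subunit of the cone channel, rose by 1.28 (SE 0.164). TBX5 (gene 100397050), a factor of dorsal retina, fell by 3.81, and VAX2 (gene 100401183), a factor of ventral retina, fell by 4.70 (adjusted p = 0.00335).

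**Figure D2:**
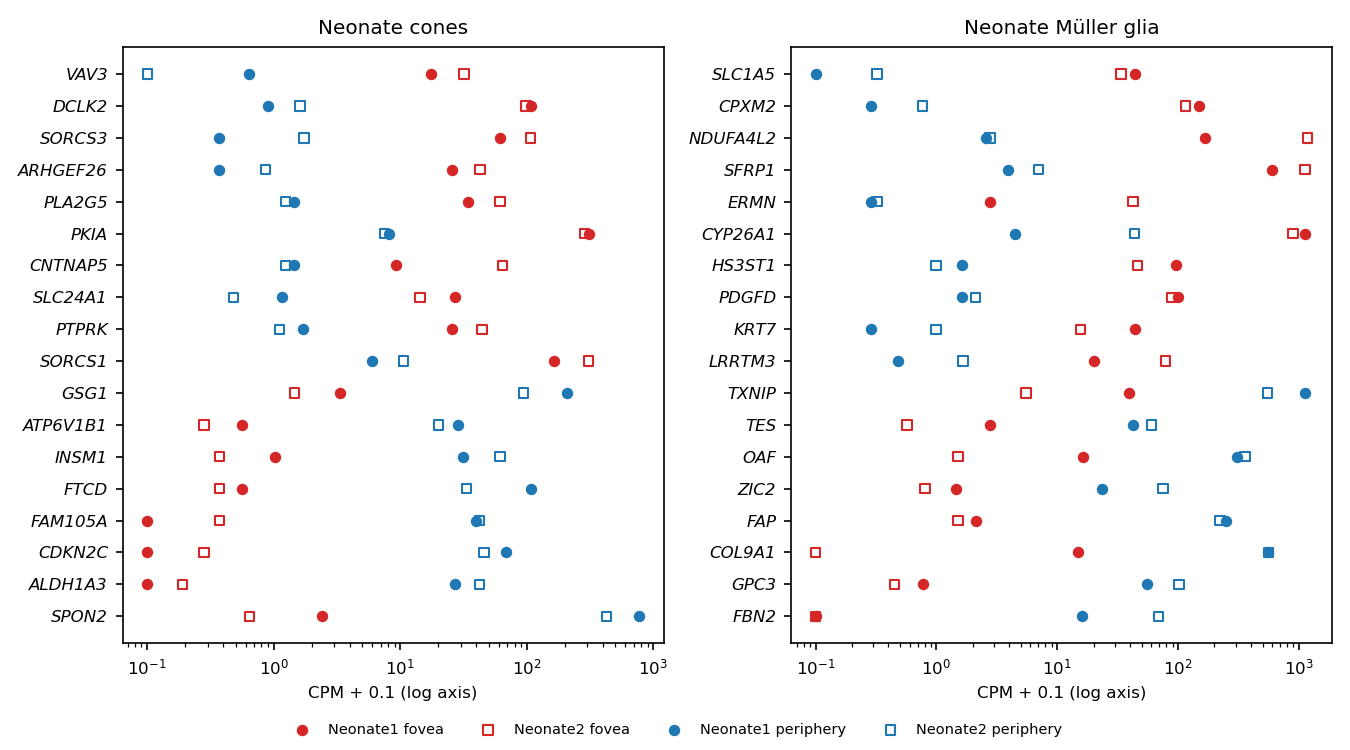
CPM plus 0.1 on a log axis of 18 of the 20 genes picked for their folds in neonate cones (left) and in Müller glia (right), with 1 point per animal and region. For each of these genes the foveal points lie on one side of both peripheral points, which the rule that picked them required within each animal.

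Of the 25 gene lists, 2 were called higher and 3 lower in foveal cones, and each of these had an adjusted p = 0.937 with an estimated correlation. Here and below, the test with an estimated correlation could hardly pass any list. Of 19 stress genes, 9 were lower and none higher over all genes, and 12 lower and 1 higher adjusted over the list alone (adjusted p = 2.8e-08, lower). The immediate-early gene FOS (gene 100390054) fell by 2.19 (SE 0.155, adjusted p = 0.000571). Of 11 BMP and TGF-beta genes, 4 were lower on either basis (adjusted p = 0.00369, lower). Of 10 retinoic acid genes, 1 was higher and 4 lower over all genes, and 1 and 6 adjusted over the list alone (adjusted p = 0.0049, lower). Of 23 glycolysis and hypoxia genes, 7 were higher and 2 lower over all genes, and 7 and 3 adjusted over the list alone (adjusted p = 0.00892, higher). Here ENO2 (gene 100409160), a neuronal enolase, rose by 2.54 (SE 0.204, adjusted p = 0.000818). Of 21 outer segment genes, 3 were higher and 1 lower over all genes, and 8 and 1 adjusted over the list alone (adjusted p = 0.0313, higher).

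The other lists did not pass in neonate cones. Among 20 regional transcription factors, 2 were higher and 5 lower over all genes, and 2 and 7 adjusted over the list alone (adjusted p = 0.0915). Among 20 cone phototransduction genes, 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone (adjusted p = 0.409), and the median log2 fold of -0.0313 and the mean of 0.174 differed in sign. Among 25 photoreceptor synapse genes, 5 were higher and 2 lower, and 9 and 2 adjusted over the list alone (adjusted p = 0.481). Among 12 WNT genes, 1 was higher and 3 lower (adjusted p = 0.409), among 14 Notch genes 2 and 2 (adjusted p = 0.569), and among 15 visual cycle genes 2 and 3 (adjusted p = 0.588). The visual cycle median was 0.11 and the mean -0.551, with the test lower. For 8 thyroid hormone genes the median was -0.274 and the mean 0.265, and 2 were higher (adjusted p = 0.588). For 13 rod phototransduction genes the median was -0.145 and the mean 0.154, and 2 were higher and 2 lower (adjusted p = 0.83). Of 7 oxidative phosphorylation genes 1 was lower (adjusted p = 0.78), and of 15 cholesterol synthesis genes (adjusted p = 0.83) and 10 cell cycle genes (adjusted p = 0.885) none passed. The cell cycle mean was 0.00698 while its test pointed lower. Markers of other classes moved too, with the summed RGC markers 2.89 log2 units and rod markers 1.15 higher in foveal cones. Of the cone calls, 13.4% were genes at least 5 times higher in another class, which leaves 813 higher and 640 lower.

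The next comparison asked the same of Müller glia, the radial glia that span the retina. They numbered 528 and 1886 in Neonate1 and 1319 and 823 in Neonate2 for fovea and periphery. Of 13679 genes, 918 were higher and 707 lower in the fovea, and 765 in all were called without CD73-depleted replicate 4 of Neonate2. SFRP1 (gene 100411463), a secreted WNT inhibitor, rose by 7.32 (SE 0.285, adjusted p = 8.55e-07), from 5.36 to 862 CPM. CYP26A1 (gene 100388379), which breaks down retinoic acid, rose by 5.90 (SE 0.693, adjusted p = 0.00039), from 24.0 to 1009 CPM. Scaled by total UMIs alone it stood at 1029 CPM in the fovea of Neonate1 and 920 in that of Neonate2, against 4.18 and 47.6 in the periphery. NDUFA4L2 (gene 100399333), a mitochondrial protein induced by hypoxia, rose by 7.58 (SE 0.522, adjusted p = 1.52e-05). SLC1A5 (gene 100408262), an amino acid transporter, was higher by a ratio of 342 (61.0 to 13500.0), and ERMN (gene 100408403) by 177 (48.7 to 1470.0). CPXM2 (gene 100399849) rose by 8.23, HS3ST1 (gene 100392281) by 5.84, PDGFD (gene 100398033), a growth factor, by 5.73, and LRRTM3 (gene 100396952) by 5.63. KRT7 (gene 100394518) rose by 5.68 and was 21.5 times higher in RGCs. FGF9 (gene 100392792), a growth factor, rose by 3.20 (SE 0.223, adjusted p = 1.58e-05) and DIO2 (gene 100406379), which activates thyroid hormone, by 2.08 (SE 0.244, adjusted p = 0.00039).

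Several matrix genes were lower in foveal Müller glia. FBN2 (gene 100393601), a fibrillin, was at least 134-fold lower. COL9A1 (gene 100403892), a collagen chain, fell by 7.47 (SE 0.956, adjusted p = 0.000634), FAP (gene 100392684), a membrane protease, fell by 7.19 (SE 0.314, adjusted p = 1.43e-06), and SPARC (gene 100414590), a matrix protein, fell by 5.65 (SE 0.431, adjusted p = 2.41e-05). RDH10 (gene 100409203), a retinol dehydrogenase, fell by 3.42 (SE 0.244, adjusted p = 1.79e-05). The BMP target ID3 (gene 100391237) fell by 4.83 (SE 0.259, adjusted p = 3.85e-06) and NR2F1 (gene 100394088), a nuclear receptor, fell by 4.63. Others were GPC3 (gene 100401118) with a log2 fold of -7.74, ZIC2 (gene 100412407) -6.21, OAF (gene 100402151) -6.07, TES (gene 100407335) -5.90 and TXNIP (gene 100397837) -5.73. The collagen gene COL4A3 (gene 100388823) rose from 3.43 to 132 CPM (adjusted p = 3.85e-06).

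In Müller glia 4 lists were called higher and 5 lower, each with an adjusted p = 0.844 with an estimated correlation. Of 16 neurofilament genes, 10 were higher and 1 lower over all genes, and 15 and 1 adjusted over the list alone (adjusted p = 4.56e-10, higher). These belong to neurons, and NEFM (gene 100410259) rose by 2.97 while 30.6 times higher in RGCs. Summed RGC markers were 3.03 log2 units higher in foveal Müller glia, and mural markers had a log2 ratio of -1.35. Of 16 FGF genes, 8 were higher and 1 lower, and 10 and 1 adjusted over the list alone (adjusted p = 8.32e-06, higher). Of 25 matrix genes, 3 were higher and 8 lower, and 5 and 9 adjusted over the list alone (adjusted p = 0.00486, lower). Of 11 angiogenesis genes, 4 were higher and 3 lower, and 5 and 4 adjusted over the list alone (adjusted p = 0.278). VEGFA (gene 100389629), the vascular growth factor, rose by 1.35 (SE 0.206, adjusted p = 0.00183). Of 10 glial reactivity genes, 3 were higher and 1 lower, and 4 and 2 adjusted over the list alone (adjusted p = 0.627). Of 18 Müller homeostasis genes, 4 were higher and 3 lower, and 4 and 4 adjusted over the list alone (adjusted p = 0.92), with a median of 0.116 and a mean of -0.0243. The regional transcription factors had a median of 0.119 and a mean of -0.431 (adjusted p = 0.278). Of the Müller calls, 16.9% were genes at least 5 times higher in another class, which leaves 711 higher and 640 lower.

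In neonate bipolar cells 900 of 16212 genes were higher and 464 lower in the fovea. The count was 252 without CD73-depleted replicate 4 of Neonate2, 842 without foveal replicate 2 of Neonate2 and 877 without foveal replicate 1 of Neonate1. CDKN2C fell by 4.93 (SE 0.355), while the heat-shock gene HSPA1A (gene 100406069) fell by 3.30 and HSPA6 (gene 100411854) fell by 3.90 and was 8.47 times higher in rods. CCK (gene 100396125), a neuropeptide, rose by 1.88 (SE 0.272, adjusted p = 2.47e-05). CA8 (gene 100401825), a carbonic anhydrase-related protein, fell by 1.47. Of the 4 genes with the largest rises, KRT7 with a log2 fold of 6.54, PRPH (gene 100393188) with 5.39 and NRN1 (gene 100402565) with 5.19 were 10.6, 14.8 and 17.1 times higher in RGCs, and COL4A3 with 5.32 was 5.25 times higher in Müller glia. CCK was among the leading genes of cluster 8 of Neonate2 and COL4A3 of cluster 15, both 99.0% foveal. Summed RGC markers were 3.22 and amacrine markers 1.04 log2 units higher in foveal bipolar cells, and 34.7% of the calls were genes at least 5 times higher in another class, which leaves 520 higher and 371 lower. Of 23 bipolar type genes, 4 were higher and 6 lower, and 6 and 6 adjusted over the list alone (adjusted p = 0.88), with a median of -0.155 and a mean of 0.1. Of 17 RGC type genes, 7 were higher and 3 lower, and 8 and 5 adjusted over the list alone (adjusted p = 0.0217, higher, and adjusted p = 0.836 with an estimated correlation).

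In neonate amacrine cells 16 of 15203 genes were higher and 21 lower. The count fell to 0 in edgeR without foveal replicate 2 of Neonate1 (1251 genes at unadjusted p under 0.05) and without CD73-depleted replicate 4 of Neonate2 (1173 genes), against 61 genes called by DESeq2 with all libraries. It was 17 without CD73-depleted replicate 2 and 191 without replicate 1 of Neonate1, 331 without foveal replicate 2 and 652 without CD73-depleted replicate 3 of Neonate2. That last library, whose class shares stood far from those of the other CD73-depleted replicates, gave 1377 of the 1854 peripheral amacrine cells of Neonate2. In the fits that called 191, 331 and 652, more genes were higher than lower. ATF3 (gene 100410420), a stress-induced factor, rose by 2.73 (SE 0.24, adjusted p = 0.0106). ALDH1A1 (gene 100407242), a retinal dehydrogenase, fell by 3.55 (SE 0.445, adjusted p = 0.0202), and RARB (gene 100396363), a retinoic acid receptor, fell by 2.77 (SE 0.272, adjusted p = 0.0106). APBB2 (gene 100409701) fell by 2.29. TTR rose by 2.42 and was 204 times higher in cones, KRT7 rose by 4.21 and was 21.3 times higher in RGCs, and C20H10orf10 (gene 100406835) rose by 1.93. Of 18 immature neuron genes 1 was lower over all genes and 9 adjusted over the list alone (adjusted p = 5.85e-10, lower, and adjusted p = 0.701 with an estimated correlation). Of the calls, 43.2% were genes at least 5 times higher in another class.

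In neonate horizontal cells 806 of 12488 genes were higher and 1115 lower, and 1178 in all without foveal replicate 1 of Neonate1. Of the 1210 peripheral horizontal cells of Neonate2, 1002 came from CD73-depleted replicate 3, whose class shares stood far from those of the other CD73-depleted replicates. Without that replicate 537 genes were higher and 773 lower. PNMT (gene 100405480), which makes adrenaline, fell by 6.26 (SE 0.373, adjusted p = 4.56e-59), and TH (gene 100393454), which makes the precursor of dopamine, fell by 5.36 (SE 0.265, adjusted p = 1.11e-85), from 361 to 7.52 CPM. Adjusted p values this small do not measure certainty over animals, since only 2 animals were compared. TH was among the leading genes of cluster 35 of Neonate1, and COL9A1 of cluster 13 of Neonate2, which held most peripheral cells and few foveal ones. DNAH5 (gene 100404721), a dynein of motile cilia, was lower by a ratio of 77.3 (21.1 to 644.0). HSPA6 fell by 4.82 and was 12.9 times higher in rods. AHRR (gene 100398664), a repressor of the aryl hydrocarbon receptor, rose by 3.73 (SE 0.344, adjusted p = 8.35e-25), FAM69C (gene 100395265) by 3.52 and CACNA2D3 (gene 100400467), a calcium channel subunit, by 3.51. TTR rose by 3.80 and was 130 times higher in cones, whose summed markers were 1.48 log2 units higher in foveal horizontal cells. COL9A1 fell by 4.43 (SE 0.251) and the FGF target ETV5 (gene 100411591) fell by 3.49. Of 19 stress genes, 1 was higher and 12 lower, and 2 and 12 adjusted over the list alone (adjusted p = 2.77e-10, lower, and adjusted p = 0.745 with an estimated correlation).

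Over the 5 classes tested in the neonates, 126 genes were higher and 115 lower in the fovea in at least 3 classes. Of these, 21 and 32 were so in at least 4 classes, and 6 and 7 in all 5 classes. The higher genes included KRT7 in 5 classes and NEFM and PRPH in 4, which were far higher in RGCs, and the Müller glia genes SFRP1 and DIO2 in 4. The lower genes included the Müller glia marker TF in 4 classes and the rod marker SAG in 3. Free RNA could add to these shared calls, which was not tested, and no number by chance was computed. Rods and RGCs were not tested between regions in the neonates, since foveal rods and the peripheral RGCs of Neonate1 were under the minimum of 20 cells. A test of RGCs among the libraries of Neonate2 alone was not made.

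A further question was how foveal cells differ between adults and neonates, with 2 animals of each age and different animals at each age. In cones 96 of 11436 genes were higher and 202 lower in the adult. The count was 121 without Adult1, 591 without Neonate1 and 0 in edgeR without Adult2 (1389 genes at unadjusted p under 0.05), against 505 genes called by DESeq2 with all animals. HK2 (gene 100396473), the hexokinase of photoreceptors, rose by 3.96 (SE 0.369, adjusted p = 0.00203), from 48.4 to 743 CPM. IL2RG (gene 100388189), a cytokine receptor chain, was at least 1250-fold higher in adult cones, HERC6 (gene 100394689) rose by 6.58 (SE 0.869), ZDHHC22 (gene 100400202) by 6.37 and ART4 (gene 100411310) by 5.45. KIF12 (gene 100410394), a kinesin, was at least 84.1-fold lower, and the matrix gene COL16A1 (gene 100393179) was lower by a ratio of 352 (63.1 to 13900.0). IBSP (gene 100413274) was lower by a ratio of 159 (43.9 to 1310.0) and C16H8orf46 (gene 100386004) by 169 (30.2 to 6680.0). The immediate-early gene EGR1 (gene 100406530) fell by 4.57 (SE 0.563, adjusted p = 0.00618). Of 23 glycolysis genes, 9 were higher over all genes, and 15 higher and 1 lower adjusted over the list alone (adjusted p = 5.14e-16, higher, and adjusted p = 0.379 with an estimated correlation). Of the calls, 10.4% were genes at least 5 times higher in another class.

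In foveal Müller glia 167 of 14373 genes were higher and 235 lower in the adult, with 8 higher and 2 lower without Adult1, 15 higher and 5 lower without Adult2 and 677 in all without Neonate1. IGFBP2 (gene 100399210), an IGF-binding protein, fell by 9.94 (SE 1.17, adjusted p = 0.00342), and CPXM2 fell by 8.44 (SE 0.61, adjusted p = 0.000244). HAPLN1 (gene 100402072), a matrix link protein, was at least 266-fold lower. ADM (gene 100387881), a vasodilator peptide, rose by 7.81 (SE 0.538, adjusted p = 0.000244) and the water channel AQP4 (gene 100409781) by 5.99 (SE 0.65, adjusted p = 0.00252). CHI3L1 (gene 100408723) was at least 86.5-fold higher, HHATL (gene 103788922) higher by a ratio of 1070 (192.0 to 42400.0) and MAL (gene 100407732) by 273 (48.6 to 10800.0). The Notch target HES5 (gene 100397404) fell by 3.20. Of 17 Notch genes, 5 were lower over all genes and 7 adjusted over the list alone (adjusted p = 0.000284, lower, and adjusted p = 0.457 with an estimated correlation). Summed rod and cone markers were 2.21 and 2.33 log2 units higher in the adult cells, and the glial reactivity genes had a median of -0.168 and a mean of 0.59 (adjusted p = 0.724). Of the calls, 9.2% were genes at least 5 times higher in another class.

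In foveal bipolar cells 66 of 15630 genes were higher and 129 lower in the adult, with 66 in all without Adult2, 516 without Neonate1 and 359 without Neonate2. Without Adult1 the balance turned, with 119 higher and 74 lower, of which 109 were called with all animals. MARCKSL1 (gene 100410948), a regulator of the cytoskeleton in growing neurons, fell by 4.49 (SE 0.456, adjusted p = 0.00279). IGSF1 (gene 100393048) fell by 6.88 (SE 0.491, adjusted p = 0.000215), MEIS3 (gene 100391207) fell by 5.34, SPON2 was lower by a ratio of 346 (118.0 to 1680.0), and NKX6-2 (gene 100387885) was at least 222-fold lower. The histamine receptor HRH1 (gene 100411714) rose by 5.36 (SE 0.732, adjusted p = 0.00823). CALCA (gene 100394886) with a log2 fold of 5.85 and C16H8orf22 (gene 100405064) with 4.46 were 7.48 and 35.6 times higher in Müller glia, and PDC (gene 100412097) with 3.06 was 28.3 times higher in cones. Summed rod and cone markers were 1.55 and 1.06 log2 units higher in the adult cells, and 19.0% of the calls were genes at least 5 times higher in another class. Of 16 immature neuron genes, 5 were lower over all genes and 8 adjusted over the list alone (adjusted p = 2.8e-11, lower, and adjusted p = 0.48 with an estimated correlation).

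In foveal RGCs 263 of 16883 genes were higher and 473 lower in the adult, with 217 higher and 208 lower without Adult1 and 255 in all without Adult2. SERPINE2 (gene 100411540), a protease inhibitor, fell by 6.70 (SE 0.307, adjusted p = 0.000319), and IGF1 (gene 100394985), a growth factor, fell by 6.96 (SE 0.574, adjusted p = 0.00353), from 228 to 1.90 CPM. GAP43 (gene 100395758), a growth cone protein, fell by 2.76 (SE 0.274, adjusted p = 0.00464). SLC6A3 (gene 100393968), the dopamine transporter, was lower by a ratio of 1960 (671.0 to 9510.0), and PLPPR3 (gene 100388532) had a log2 fold of -7.34. KCNJ3 (gene 100410336), a potassium channel, rose by 3.72 (SE 0.343, adjusted p = 0.00423) and KCNA1 (gene 100395602) by 2.51. ADM rose by 6.96 and was 9.16 times higher in Müller glia, BAG3 (gene 100414326) rose by 4.80 and C20H10orf10 by 3.95. Of 24 glycolysis genes 6 were higher over all genes and 15 adjusted over the list alone (adjusted p = 9.23e-13, higher). Of 17 immature neuron genes, 8 were lower over all genes, and 10 lower and 1 higher adjusted over the list alone (adjusted p = 4.28e-12, lower). Each had an adjusted p = 0.198 with an estimated correlation. Summed rod markers stood at 95.6 CPM in the adult cells and 24.6 in the neonate ones, cone, amacrine and mural markers had log2 ratios of 1.44, -1.17 and -1.97, and 15.9% of the calls were genes at least 5 times higher in another class.

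The adult fovea was compared with the adult periphery in 2 libraries of each region from Adult2, to see which regional differences are present after development. Its p values measure the spread between libraries of 1 animal and not between animals. Region and sorting cannot be told apart here either. In cones 2133 of 8918 genes were higher and 1878 lower in the fovea. PKIA rose by 6.35 (SE 0.275, adjusted p = 8.46e-114), from 2.46 to 211 CPM, and HK2 by 4.07 (SE 0.115, adjusted p = 1.35e-261). DPP4 (gene 100393303), a membrane peptidase, and GRXCR1 (gene 100404498), a protein of actin bundles, were each at least 22.0-fold higher, and PRKAA2 (gene 100396565), a subunit of the energy sensor AMPK, higher by a ratio of 67.4 (22.4 to 332.0). MDGA1 (gene 100393141) was at least 34.3-fold lower, ALDH1A3 at least 33.6-fold and LDLRAD3 (gene 100393345) at least 28.4-fold. CALB1 (gene 100406048), a calcium-binding protein, fell by 3.72 (SE 0.0985, adjusted p = 7.72e-297). Of 22 glycolysis genes, 17 were higher and 1 lower on either basis, over all genes and adjusted over the list alone (adjusted p = 4.62e-17, higher, and adjusted p = 0.241 with an estimated correlation). Summed RGC markers were 3.41 log2 units higher in foveal cones and rod markers 0.133. Bipolar, Müller glia and mural markers had log2 ratios of -1.39, -1.34 and -1.08. Of the calls, 9.55% were genes at least 5 times higher in another class, which leaves 1841 higher and 1787 lower.

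In adult Müller glia 2875 of 12512 genes were higher and 3134 lower in the fovea. The test used 1158 peripheral cells. A further 1164 CD73-depleted cells nearest to Müller glia, in cluster 12, had stayed unnamed and were not tested. With clusters put back, 3140 genes were higher and 3518 lower in the fovea. COL9A1 was at least 1390-fold lower, and LCN2 (gene 100403491), a protein of reactive glia, at least 103-fold lower. SPARC fell by 8.48 (SE 0.11, adjusted p = 1.85e-33), RDH10 fell by 6.15 (SE 0.098, adjusted p = 2.93e-31) and RLBP1 (gene 100408400), a retinal carrier of the visual cycle, fell by 2.05 (SE 0.0472, adjusted p = 5.47e-27). SFRP1 was higher by a ratio of 1220 (218.0 to 48000.0), SMPX (gene 100405234) by 468 (83.6 to 18500.0), SHISA9 (gene 100396224) was at least 110.0-fold higher and CYP26C1 (gene 100388017), an enzyme that breaks down retinoic acid, at least 109-fold higher. CYP26A1 rose by 4.44 (SE 0.0643, adjusted p = 3.01e-32) and FGF9 by 4.54 (SE 0.0981, adjusted p = 8.63e-28). Of 11 visual cycle genes, 8 were lower over all genes, and 8 lower and 1 higher adjusted over the list alone (adjusted p = 2.72e-18, lower). Of 21 matrix genes, 3 were higher and 12 lower on either basis, including adjusted over the list alone (adjusted p = 1.49e-14, lower). Each had an adjusted p = 0.108 with an estimated correlation. The summed Müller glia markers, which include RLBP1, had a log2 ratio of -1.19 in the foveal cells. Summed RGC markers were 3.21 log2 units higher in the foveal cells, rod, bipolar and mural markers had log2 ratios of -1.30, -1.18 and -1.41, and 11.4% of the calls were genes at least 5 times higher in another class, which leaves 2479 higher and 2845 lower.

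In adult bipolar cells 2408 of 13604 genes were higher and 2442 lower in the fovea. EPSTI1 (gene 100401749) rose by 6.89 (SE 0.169, adjusted p = 8.57e-15), from 1.11 to 134 CPM, and IGSF10 (gene 100394806) was at least 105-fold higher. CCK rose by 2.49 (SE 0.104, adjusted p = 1.27e-11) and CA8 fell by 3.56 (SE 0.0837, adjusted p = 5.22e-15). EPSTI1, IGSF10 and CCK were among the leading genes of cluster 6 of Adult2, which was 98.7% foveal, and CA8 led cluster 19, which was 4.02% foveal. IGFBP5 (gene 100412845) with a log2 fold of 4.76 and C16H8orf22 with 4.64 were 64.7 and 19.2 times higher in Müller glia. ID3 with -3.58 and SFRP2 (gene 100402798) with -3.50 were 43.2 and 52.7 times higher in Müller glia. Of 17 neurofilament genes, 13 were higher and 2 lower, and 13 and 3 adjusted over the list alone (adjusted p = 4.28e-51, higher, and adjusted p = 0.0914 with an estimated correlation). The RGC type genes had a median of 0.636 and a mean of 0.992 while their test pointed lower (adjusted p = 0.908). Summed RGC and amacrine markers were 2.92 and 1.06 log2 units higher in the foveal cells, rod and mural markers had log2 ratios of -1.23 and -1.14, and 16.1% of the calls were genes at least 5 times higher in another class, which leaves 1873 higher and 2194 lower.

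In adult RGCs, with 26 and 31 peripheral cells, 604 of 12737 genes were higher and 517 lower in the fovea. Foveal RGCs lay mostly in clusters 3 (65.2%, led by KRT7) and 23 (16.8%, led by WFDC2) of Adult2, and peripheral ones in clusters 8 (43.9%) and 27 (28.1%). A further 65 CD73-depleted cells nearest to RGCs, in cluster 28, had stayed unnamed and were not tested. With clusters put back the balance turned, with 1498 higher and 1759 lower. The balance also turned without foveal library 1, with 178 higher and 198 lower, and without foveal library 2, with 245 higher and 301 lower. The count was 0 in edgeR without either peripheral library (1697 genes at unadjusted p under 0.05 without library 1 and 1809 without library 2), against 911 called by DESeq2 with all libraries. TNNI1 (gene 100398085), a troponin, rose by 4.87 (SE 0.302, adjusted p = 1.22e-08), from 9.33 to 270 CPM. WFDC2 (gene 100401860) was higher by a ratio of 27.8 (4.98 to 1100.0), KRT7 by 22.5 (6.21 to 186.0) and GFY (gene 100409831) by 12.1 (4.14 to 59.0). FREM3 (gene 100405327) was at least 138-fold lower, and FAM163A (gene 100385781) fell by 5.34 and DCC (gene 100410745), a netrin receptor, fell by 4.93 (SE 0.687, adjusted p = 0.00017). ID3 fell by 4.88 and was 50.7 times higher in Müller glia. EGLN3 (gene 100389821), a hypoxia-induced enzyme, rose by 3.59 (SE 0.403, adjusted p = 1.87e-05), and SERPINF1 (gene 100403187), an anti-angiogenic factor, fell by 2.54 (SE 0.284, adjusted p = 1.87e-05). Of 8 rod phototransduction genes 6 were lower over all genes and 7 adjusted over the list alone (adjusted p = 6.28e-28, lower, and adjusted p = 0.103 with an estimated correlation). Summed rod, bipolar, Müller glia and mural markers had log2 ratios of -2.13, -1.78, -1.59 and -1.79 in the foveal cells, and 135 of the calls were genes at least 5 times higher in another class, which leaves 571 higher and 415 lower.

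The regional folds of neonates and the adult were then compared over genes measured at both ages. Genes are not independent replicates. In cones, 618 of 1142 neonate calls (54.1%) had the same sign in the adult, and the folds had a Pearson r of 0.319 and a Spearman rho of -0.0189 across genes. Called at both ages were 258 genes higher (174 by chance), 161 lower (86.8 by chance) and 300 with opposite signs (252 by chance). In Müller glia 1166 of 1431 calls (81.5%) had the same sign, r was 0.564 and rho 0.336, with 524 genes higher (188 by chance), 428 lower (149 by chance) and 142 opposite (341 by chance). In bipolar cells 922 of 1160 (79.5%) had the same sign, r was 0.5 and rho 0.299, with 466 higher (143 by chance), 190 lower (62.7 by chance) and 86 opposite (205 by chance). A joint edgeR fit of 3 animals with a term for age by region called 656 genes in cones, 471 in Müller glia and 353 in bipolar cells, of which 558, 310 and 231 had fitted folds of opposite sign at the 2 ages. That fit has 6 units and 1 residual degree of freedom, and a single adult.

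**Figure D3:**
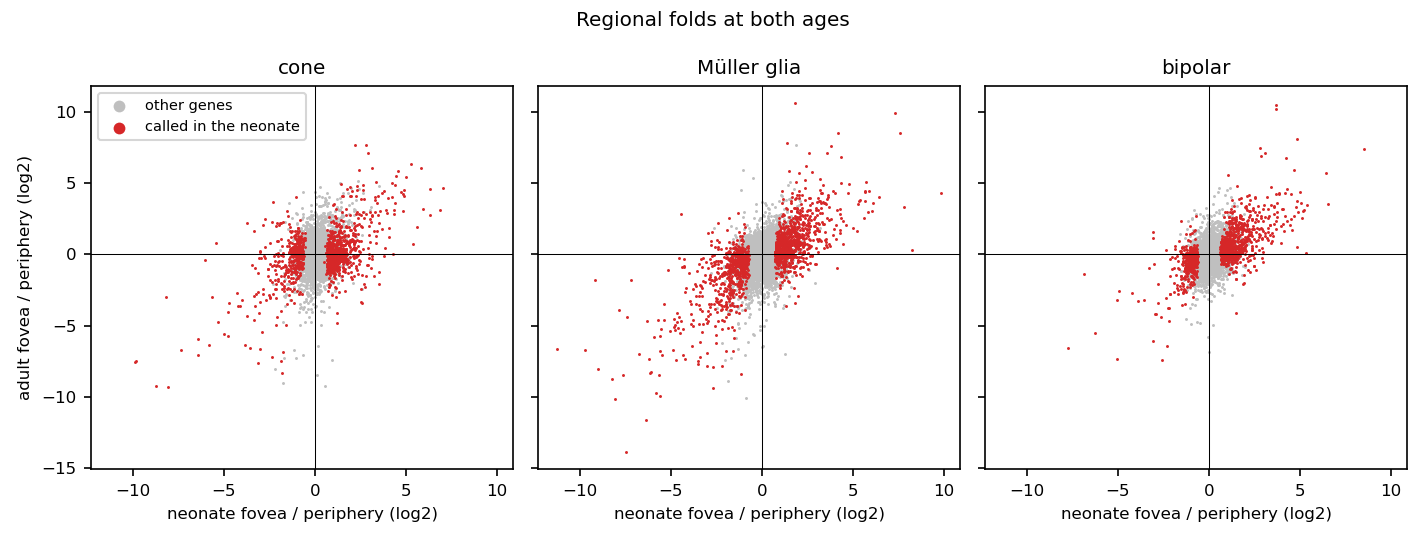
Log2 fold of fovea over periphery in the adult (vertical axis) against the neonate (horizontal axis) for genes measured at both ages, with genes called in the neonate in red. Spearman's rho across genes was -0.0189 in cones, 0.336 in Müller glia and 0.299 in bipolar cells.

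Among the neonate genes named for their large folds, 14 of 14 cone genes measured in the adult had the same sign there, and 13 of them were called. VAV3, CNTNAP5, SPON2, FAM105A, FTCD and INSM1 did not pass the adult expression filter. In adult cones SLC24A1 had a log2 fold of 4.05, SORCS1 3.05 and GSG1 -0.37 (adjusted p = 0.227). In Müller glia 17 of 17 had the same sign and 16 were called, and SLC1A5 had 0.32 (adjusted p = 0.327). CPXM2, ERMN and GPC3 did not pass the adult filter. In Adult2 ERMN had 0 UMIs in foveal and 6 in peripheral Müller glia, and GPC3 had 4 and 2. MDGA1 had 67 UMIs in foveal and 39 in peripheral cones of the neonates, and 0 and 212 in those of Adult2. In bipolar cells 8 of 8 had the same sign and 7 were called, and COL4A3 had 0.06 (adjusted p = 0.809). In the neonates KRT7, PRPH and NRN1 were at least 5 times higher in RGCs, COL4A3 in Müller glia and HSPA6 in rods. Summed RGC markers were 3.22 log2 units higher in foveal bipolar cells of the neonates and 2.92 in those of the adult. Free RNA at both ages could add to this agreement, which was not tested. Scaled by total UMIs alone, CYP26A1 in foveal Müller glia stood at 2257 CPM in Adult1 and 4386 in Adult2, and at 193 in the periphery of Adult2.

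**Figure D4:**
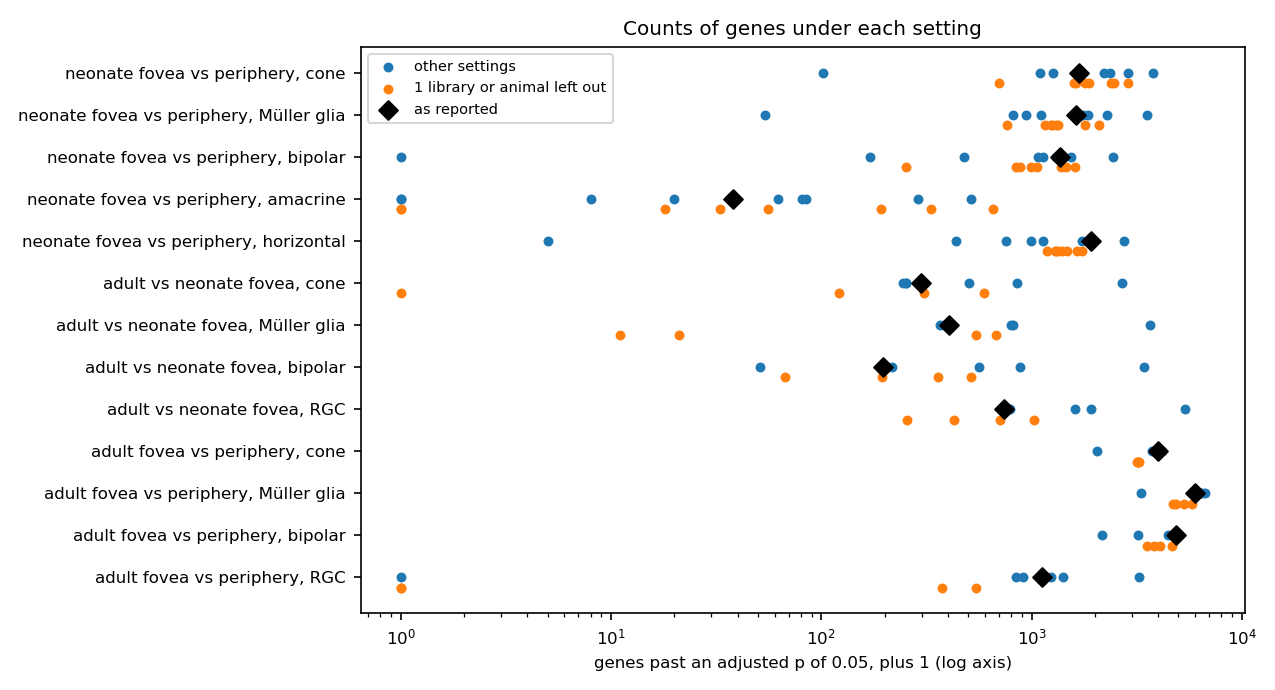
Genes past an adjusted p of 0.05, plus 1, on a log axis in each comparison as reported (black), with other settings (blue) and with 1 library or animal left out (orange). In neonate cones the count runs from 101 without the animal block to 3770 with libraries as units.

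The chromatin samples of Neonate3 ask which regulatory regions are open in each part of the retina, with 1 animal and no test between regions. Fovea replicates 1 and 2 held 1127 and 7869 nuclei with medians of 3181 and 4057 counts, and periphery replicates 1 and 2 held 6134 and 9783 with medians of 10259 and 6657. Of 30707 peaks of fovea replicate 1, 11043 (36.0%) overlapped a peak of periphery replicate 2, and of 70772 peripheral peaks 11110 (15.7%) overlapped a foveal one. Foveal peaks covered 26862062 bp and peripheral peaks 64754511 bp. The smaller foveal list bears on the lower share of peripheral peaks. It does not account for the foveal peaks without an overlap, whose cause was not tested. Fovea replicate 2 had 71314 peaks in its counts, so the 30707 of replicate 1 do not stand for the fovea as a whole. Shared foveal peaks had a mean of 204 counts against 70.4 for the others, and shared peripheral peaks 2139 against 754. The foveal peak with most counts (148866) lay on chromosome 1 from 62368853 to 62370169 and overlapped the leading peripheral peak, from 62368100 to 62370169 with 334057 counts. The foveal count is out of 3634180 in 1127 nuclei, and why it is so high was not tested. The leading foveal peak without an overlap lay on chromosome 8 from 53498925 to 53499672 with 19326 counts. This count is also high for 1127 nuclei, for reasons not tested, so the peak is not shown to be a region open in the fovea alone. The leading peripheral peak without an overlap lay on chromosome 22 from 3442540 to 3445686 with 20728 counts. The genes at these positions were not analysed here.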

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

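The test of genes with few counts was chosen after its result had been seen, though its minimum of 20 CPM was planned. Leaving out genes higher in adult rods was added after the data had been seen, with its test written before its own result, and the intervals of rho were added after the values of rho had been seen. The use of other libraries in weighing CD90 selection was also added after its values had been seen, and the other tests weighed here were written before. In groups of 4 to 10 replicates, 33 sets of values were looked at for 1 replicate far from the rest, and 7 stood apart. Chance alone gives about 1 in 20, or 1.65 of the 33. Foveal replicate 2 of Adult1 had 15336854 UMIs, and the next lowest of the 5 adult foveal replicates 21377727. Foveal replicate 1 of Adult2 had 19.4% Müller glia, with 17.6% in the next. Foveal replicate 2 of Neonate1 had 0.375% rods, with 0 in the other neonate foveal replicates, and 21.8% unnamed cells, with 5.92% in the next.

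The remaining 3 of the 7 lie in CD73-depleted replicate 3 of Neonate2. It held 56.2% RGCs where the nearest replicate held 0.984%, 13.5% horizontal cells where the nearest held 2.84%, and 0.296% bipolar cells where the nearest held 41.9%. A foveal library under a peripheral label is argued against, because at 78.9% of 2886 genes called between regions without this library (77.4 to 80.4) its cones lay nearer to the peripheral replicate 4 than to foveal cones of the same animal. In Müller glia this share was 77.9% of 1789 genes. Cells selected for CD90 stay open, since values go both ways. The change in class share had a Spearman rho of 0.679 with the level of THY1, the gene of CD90, over 7 classes (exact p = 0.11), and RGCs led in both. Bipolar cells had 187 CPM of THY1, against 2050 in RGCs, and a log2 share ratio of -7.16. Their THY1 may be free RNA of RGCs, since summed RGC markers stood at 2298 CPM in neonate foveal bipolar cells and 25990 CPM in RGCs. The bipolar value therefore does not count against the selection. The CD90-positive library of the same animal held 78.2% mural cells and 0.21% RGCs, which goes against such a selection. The adult library labelled CD70p, whose deposited file is named CD90, held 30.4% RGCs, 60.1% amacrine cells and 0.296% bipolar cells, which goes with it if that name is right. A difference in dissection was not tested.

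Between ages, the term for age by region in edgeR found fitted folds of opposite sign that differ at 558 genes in cones, 310 in Müller glia and 231 in bipolar cells. The sign at each age was not itself tested. Among named genes these were ERMN in Müller glia, with a fitted adult minus neonate log2 difference of -12.18, GPC3 in Müller glia with 8.21, and MDGA1 in cones with -12.18. These fitted values have no firm size, since foveal cells of Adult2 had 0 UMIs of ERMN and MDGA1 and 4 of GPC3, with 6 of ERMN and 2 of GPC3 in peripheral Müller glia. The adult sign of GPC3 is not established by so few UMIs. Over genes the cone folds of neonate and adult were unrelated in rank. Noise of genes with few counts is argued against, because rho was -0.118 (95% interval -0.143 to -0.0928, with genes taken as independent) over genes of at least 20 CPM. Rod RNA in the peripheral cones of the adult stays open, since values go both ways. Summed rod markers stood at 7438 CPM in foveal and 6783 CPM in peripheral cones of Adult2, so they show no excess in the periphery. Leaving out 3113 genes higher in adult rods moved rho from -0.0189 to 0.083 (0.0572 to 0.109) and the Pearson r from 0.319 to 0.405, as such RNA would, and this rho lies below the bound set for rod RNA as the cause but not below the one set against it by more than its interval. A regional difference that changes with age is consistent with the 656 genes called for the age by region term in cones. It remains a hypothesis, since a single adult has both regions and animal, age and library batch are not separable in it.

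Signals also appeared in libraries that no test used. The CD90-positive library of the neonate was 78.2% mural cells. The adult library labelled CD70p was 60.1% amacrine cells and 30.4% RGCs, and the NeuN-positive nuclei were 19.5% RGCs.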

How the results depend on the processing

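The alternatives that left out genes at least 5 times higher in another class, left out genes higher in adult rods, put clusters back, or used replicate number as block in the adult were chosen after seeing the data. Of 13288 values of named genes under the alternatives, 11302 kept their sign and their side of the threshold, 1984 kept the sign and no longer passed, and 2 reversed. In adult RGCs these were FGF12, at -0.21 with clusters put back, and SPARCL1, at 0.48 without CD73-depleted replicate 2 and -1.54 without replicate 1. The genes were named because they passed in these same data, so few reversals were likely from the start. Values are missing where a setting did not test the gene. Without the animal block, 387 of 425 values of the neonate regional comparisons no longer passed. The neonate regional comparisons of rods and RGCs were not run under any setting. Where a count moved by more than 1.5 times, the cause was not tested unless given here.

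The animal block decided most neonate calls. Without this replicate block the counts were 101 in cones, 53 in Müller glia, 4 in horizontal cells, and in edgeR 0 in bipolar cells (1040 at unadjusted p under 0.05) and 0 in amacrine cells (420), where DESeq2 with the block called 478 and 61. With libraries as units and animal as replicate block they were 3770 in cones, 3545 in Müller glia, 2450 in bipolar cells and 289 in amacrine cells. With libraries as units the age counts were 2686 in cones, 3646 in Müller glia, 3443 in bipolar cells and 5398 in RGCs, and such units treat libraries of 1 animal as independent.

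DESeq2 called 1092 genes in neonate cones, 815 in Müller glia, 478 in bipolar cells, 61 in amacrine cells and 435 in horizontal cells. For age it called 505 in cones, 814 in Müller glia, 564 in bipolar cells and 1607 in RGCs, and for the adult regions 2047 in cones, 3315 in Müller glia and 2153 in bipolar cells. With DESeq2 the share of calls that were higher was 43.2% and not 32.2% in age cones, and 50.2% and not 33.8% in age bipolar cells. It was 29.0% and not 42.0% in neonate horizontal cells, 44.7% and not 35.7% in age RGCs and 43.9% and not 53.9% in adult RGCs. RLE scaling gave 7 in amacrine cells. Without the expression filter the counts were 2885 in neonate cones and 516 in amacrine cells, and for age 853, 801, 878 and 1921 in cones, Müller glia, bipolar cells and RGCs. In the adult they were 3217 in bipolar cells and 0 in RGCs in edgeR (2417 at unadjusted p under 0.05), where DESeq2 with the filter called 911.

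Requiring 1000 genes per cell gave 80 in amacrine cells, 1138 in horizontal cells and 50 in age bipolar cells. It moved neonate foveal shares to 11.4% cones, 21.6% bipolar cells and 29.6% RGCs, and adult ones to 21.2% Müller glia, 28.1% bipolar cells, 28.1% RGCs and 9.58% amacrine cells. With doublets kept the counts were 942 in Müller glia, 84 in amacrine cells and 997 in horizontal cells, with shares of 10.0% neonate cones, 0.231% neonate rods and 36.0% adult bipolar cells. Units thinned to 1 depth gave 170 in bipolar cells, 757 in horizontal cells and 0 in amacrine cells in edgeR (865 at unadjusted p under 0.05), against 61 by DESeq2 at full depth. Calls also fell to 1263 in cones and 1110 in Müller glia. Thinning left fewer genes to test, with 10636 and not 16212 in bipolar cells. It shows only that fewer UMIs give fewer calls. Leaving out genes called the same way in 3 or more other classes left 19 in amacrine cells. Leaving out genes 5 times higher in another class left 891 in bipolar cells (520 higher and 371 lower) and 21 in amacrine cells. Clusters put back gave 3257 in adult RGCs, with 1498 higher and 1759 lower, against 604 and 517 without them.

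With 1 library left out at a time, neonate counts ranged from 699 to 2886 in cones, 765 to 2088 in Müller glia, 252 to 1607 in bipolar cells, 0 to 652 in amacrine cells (1251 at unadjusted p under 0.05 in edgeR at the lowest, against 61 by DESeq2 with all libraries) and 1178 to 1736 in horizontal cells. With 1 animal left out, which leaves an age with a lone animal assumed to vary like the others, age counts ranged from 0 to 591 in cones (1389 at unadjusted p under 0.05 in edgeR at the lowest, against 505 by DESeq2 with all animals), 10 to 677 in Müller glia, 66 to 516 in bipolar cells and 255 to 1026 in RGCs. Adult counts ranged from 3188 to 3244 in cones, 4713 to 5770 in Müller glia, 3556 to 4667 in bipolar cells and 0 to 546 in RGCs (1697 at unadjusted p under 0.05 in edgeR at the lowest, against 911 by DESeq2 with all libraries). The lowest neonate counts came without CD73-depleted replicate 4 of Neonate2, in amacrine cells also without foveal replicate 2 of Neonate1, and in horizontal cells without foveal replicate 1 of Neonate1. The highest came without CD73-depleted replicate 3 of Neonate2 in cones and amacrine cells, without foveal replicate 1 of Neonate2 in Müller glia and bipolar cells, and without CD73-depleted replicate 2 of Neonate1 in horizontal cells. For age the lowest came without Adult2, in Müller glia without Adult1, and the highest without Neonate1. The 0 of adult RGCs came without either peripheral library.

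For the comparison of ages, genes of at least 20 CPM gave a rho of -0.118 in cones and 0.235 in bipolar cells, and leaving out genes higher in adult rods gave 0.083 in cones, with a Pearson r of 0.405. A reciprocal overlap of 50% gave 33.3% of foveal and 14.5% of peripheral peaks shared, and the upper part of peaks by counts 33.2% and 14.6%.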

Other observations

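No test in this part was chosen after its result was seen. DIO2, CYP26A1 and SFRP1, which are Müller glia genes higher in the fovea, were also higher in foveal cones and bipolar cells, and DIO2 and SFRP1 in horizontal cells, where CYP26A1 did not pass the expression filter. If free RNA of foveal Müller glia were the source, these genes would stand at the share of the Müller level that Müller markers have in the same cells. Their share was 0.885 of that of the markers, as a median over the 3 genes, 3 classes and 2 animals with CYP26A1 in horizontal cells included, so free RNA may account for these calls. The level of CYP26A1 was 3.99 CPM in foveal cones of Neonate1 and 1029 CPM in its foveal Müller glia. Expression in the cones themselves was not tested apart from this, and no biological explanation was tested.

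Pairs of replicate libraries differed in their counts per gene by 2.15 to 31.5 times the value that counting error gives, as chi-square per degree of freedom over genes, except CD73-depleted replicates 3 and 4 of Neonate2 with 436. Chromatin counts differed in depth between regions, with a median of 3181 counts per nucleus in fovea replicate 1 and 6657 in periphery replicate 2.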
